A study of Mus musculus with 40 samples.

How the data were processed

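Adult globin transcripts were counted in 40 RNA-seq libraries from 20 mice. Each library came from Ter119+ erythroid cells, isolated with anti-Ter119 magnetic beads from bone marrow or spleen, and the kit was a stranded total RNA kit, per the labels' protocols. The 8 groups of 5 libraries combined tissue, genotype (wild type, WT, or heterozygous Hbb th3, written th3/+) and Hbb haplotype. The single haplotype carries Hbb-bs and Hbb-bt, and the diffuse haplotype carries Hbb-b1 and Hbb-b2.

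The values were raw read counts per gene as deposited by the authors, separately for exons and introns. STAR 2.7.9a, STAR 2.5.3a, SAMtools, HTSeq and the mm10 build are named in the submitters' processing notes, without their roles. The strand setting and the treatment of multiply mapped reads were not given in the sources used here. Columns headed Hbb-single, Hbb-diffuse and Ambiguous were taken to hold reads that could not be divided between the genes of a pair. The pairs were taken as Hbb-bs with Hbb-bt, Hbb-b1 with Hbb-b2, and Hba-a1 with Hba-a2. The headers name these columns but do not state this meaning. The table listed only adult globin genes, so no library total over all genes was used, and embryonic globins were not analysed here. The authors' deposited ratio of alpha to beta counts differed from the summed counts by at most 0.00109. The authors' fraction of Hbb-b2 and their percent of intron over exon counts equalled the values recomputed from the counts. These derived columns served only as these checks.

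Adult beta counts were the sum of the exon counts of all 4 beta genes with the reads shared within a pair, and adult alpha counts the sum of Hba-a1, Hba-a2 and their shared reads. The beta/alpha ratio is the quotient of these sums within a library, which needs no scaling for library size but keeps any difference between the genes in length, mappability or library yield, so that its level is not a ratio of molecules. The second-gene share is Hbb-bt among Hbb-bs plus Hbb-bt, or Hbb-b2 among Hbb-b1 plus Hbb-b2, over uniquely assigned exon counts. Shared reads took 14.1% to 18.6% of beta counts in single libraries, at most 0.0114% in diffuse libraries, and 28.3% to 36.3% of alpha counts. In the GENCODE M21 annotation of mm10 the coding sequences of Hbb-bs and Hbb-bt differ at 1 of 441 positions, and those of Hba-a1 and Hba-a2 at 1 of 426, so the division of reads within these pairs is uncertain. Exon counts summed to between 10110962 and 32381045 per library, so counting error was small beside the spread between mice.

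Groups were compared on log2 ratios or log2 odds with two-sided exact permutation tests over all 252 splits of 5 against 5, whose smallest p is 0.00794. Intervals are 95% intervals from inverting that test. Folds and percent changes of these comparisons come from differences in mean log2 values. They can differ slightly from quotients of the arithmetic group means printed beside them. Whether the th3/+ effect differed between haplotypes was tested by permuting residuals of the additive model 100000 times. P-values were adjusted by Benjamini-Hochberg within each family, with 4 tests in most families and 2 for the difference between haplotypes, and 0.05 was the threshold. Single genes were tested with edgeR's quasi-likelihood test on all 40 libraries, with the alpha sum as offset and no TMM factors, adjusted over 68 tests of 9 features and 8 contrasts. The other 4 combinations, all of reads shared within a beta pair, gave no usable standard error and were left out. Some of the 68 tests compared haplotypes for beta features that 1 of the groups did not carry, so their outcome was fixed in advance. They lower the adjusted p of the other tests, so edgeR calls near the threshold are less sure. All listed genes are named, as fixed before the data were examined. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

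Then 20 data sets of the 9 features were simulated, with beta genes at a fold of 0.5 in th3/+ against WT. In these edgeR called 160 of 160 changed genes and 6 of 240 unchanged alpha tests. All features had the same simulated dispersion of 0.02, and alpha counts were drawn apart from the offset, whereas real alpha counts sum to it. With all 40 libraries in the fit, Hbb-bs had an SE of 0.44 in spleen. The simulation thus does not show the power for that gene. That fit included the diffuse libraries, which had only 363 to 9253 Hbb-bs counts. In single spleen libraries Hbb-bs per alpha count was 1.40 ± 0.136 in WT and 0.829 ± 0.0613 in th3/+ (SD, n = 5 each). Hbb-bt per alpha count was 0.356 ± 0.0344 and 0.221 ± 0.0128 there. The SE of 0.44 is thus no sign of a larger spread among the libraries that carry Hbb-bs. The permutation interval held the simulated fold in 98.8% of 80 cases. In 400 data sets without an effect, the exact test gave p under 0.05 in 3% and the residual permutation in 5.25%.

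Rows of the table named the group and a mouse code but no replicate number, so libraries are numbered here from 1 to 5 within a group in the order of the codes. The same 20 codes occurred once in bone marrow and once in spleen and were taken as the mouse. Deviations from the group mean in the log2 beta/alpha ratio were not correlated between the tissues of a mouse over the 20 mice (Pearson r = 0.0219, permutation p = 0.919; Spearman rho = 0.191, permutation p = 0.417; r = 0.0982 without the 2 mice farthest from the median). Pairing by mouse was an alternative for the comparison of the tissues. The codes fell into 2 series: 4 of the 5 WT single mice had codes of one series, and the other 16 mice had codes of the other. No 2 libraries of a group agreed within sampling noise, the smallest chi-square per degree of freedom being 144.

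Alternatives were Hba-a1 or Hba-a2 alone as the denominator, the linear scale, limma, edgeR on the summed beta counts, other offsets, TMM factors, a count filter, each tissue fitted alone, DESeq2 and leaving out each library. Chosen after seeing the data were sums of uniquely assigned counts, sums over the genes of the haplotype carried, sums of exon and intron counts, edgeR on only the groups compared, and the pairing by mouse code. So were the test of whether the second-gene effect differed between haplotypes, the comparison of ratios by code series, and the look at counts assigned to the genes of the other haplotype, per beta or per alpha count. The same holds for naming the reads shared by the alpha genes.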

Results

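Adult alpha- and beta-globin transcripts were measured by RNA-seq in Ter119+ erythroid cells, which carry the Ter119 surface antigen of the red cell lineage, from the bone marrow and the spleen of 20 mice. The mice were wild type (WT) or Hbb th3/+, a model of beta-thalassemia with a heterozygous deletion of adult beta-globin genes. They carried the single or the diffuse beta-globin haplotype. Each of the 8 combinations of tissue, genotype and haplotype had 5 libraries. Exon counts over the listed globin genes summed to between 10110962 and 32381045 per library. The study asked to what degree the haplotypes modify the severity of the disease. In mm10, Hbb-bs (ENSMUSG00000052305.6) lies on the minus strand of chromosome 7 from 103826534 to 103828096. Hbb-bt (ENSMUSG00000073940.3) lies on the same strand from 103812524 to 103813996. Hba-a1 (ENSMUSG00000069919.7) lies on the plus strand of chromosome 11 from 32283511 to 32284465. Hba-a2 (ENSMUSG00000069917.7) lies on the same strand from 32296489 to 32297298. Each of these 4 genes has 3 exons and 2 introns. Hbb-b1, the beta-major gene, and Hbb-b2, the beta-minor gene, form the diffuse haplotype and have no position in the annotation used.

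Beta-globin mRNA was lower relative to alpha-globin mRNA in th3/+ than in WT erythroid cells in both tissues and on both haplotypes. In bone marrow of the single haplotype the ratio of adult beta to adult alpha counts was 2.60 ± 0.357 (SD, n = 5) in WT and 1.17 ± 0.132 (SD, n = 5) in th3/+. It fell by 55.1%, a change taken from the mean log2 ratios, as are the percents below, whereas the group values are arithmetic means. On the diffuse haplotype it was 3.21 ± 0.572 (SD, n = 5) in WT and 1.42 ± 0.0647 (SD, n = 5) in th3/+. It fell by 55.3%. In spleen the ratio fell by 41.4% on the single haplotype, from 2.12 ± 0.178 to 1.25 ± 0.0985 (SD, n = 5 each). It fell by 49.0% on the diffuse haplotype, from 2.94 ± 0.463 to 1.49 ± 0.0656 (SD, n = 5 each). In each of the 4 comparisons all 5 th3/+ libraries lay below all 5 WT libraries. The two-sided exact permutation p was 0.00794, the smallest the design allows, as was the adjusted value. The log2 differences were -1.16 (95% interval -1.42 to -0.88) and -1.16 (-1.43 to -0.95) in bone marrow of the single and diffuse haplotypes. In spleen they were -0.77 (-0.94 to -0.58) and -0.97 (-1.19 to -0.81). The only WT single mouse whose code belonged to the series of all th3/+ mice had ratios of 2.66 in bone marrow and 2.14 in spleen. These lay within the ranges of 2.04 to 2.92 and 1.88 to 2.35 of the other 4 WT single mice.

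**Figure D1:**
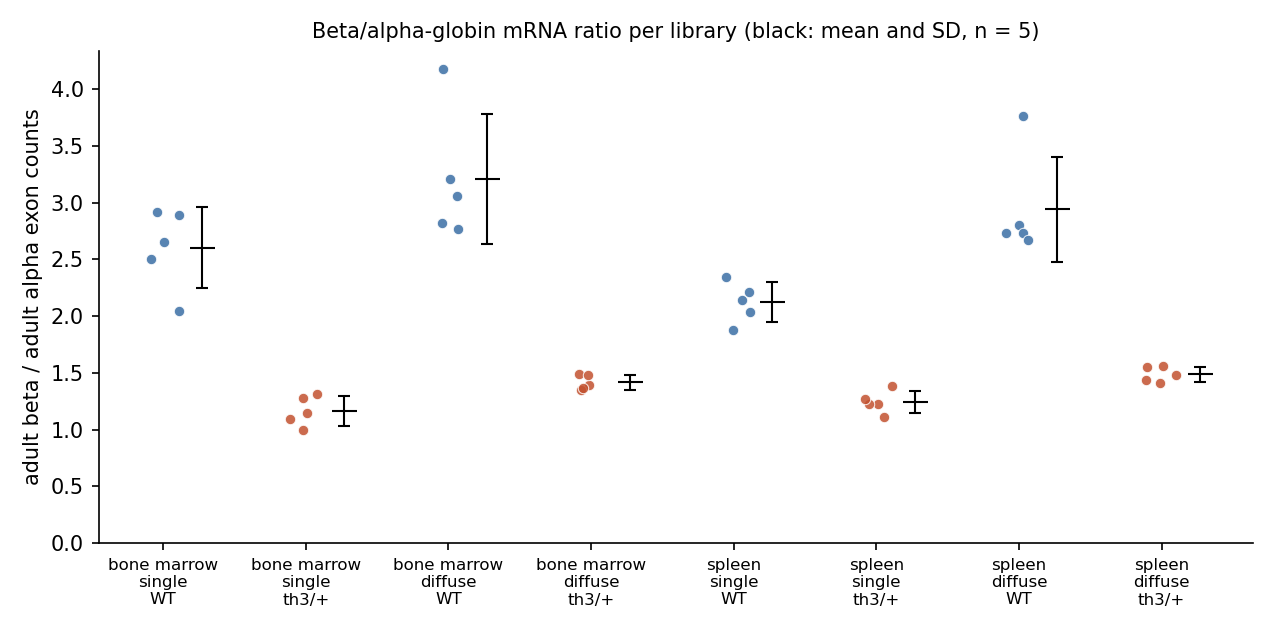
Ratio of adult beta- to adult alpha-globin exon counts (vertical axis, no unit) for each library, by tissue, haplotype and genotype, with WT in blue and th3/+ in red, and group mean and SD in black (n = 5). The th3/+ libraries lie between 0.995 and 1.56 and the WT libraries between 1.88 and 4.18.

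The diffuse haplotype had the higher beta/alpha ratio in each tissue and genotype. Among th3/+ libraries the ratio was 1.22-fold higher (95% interval 1.06 to 1.38) on the diffuse haplotype in bone marrow. It was 19.7% higher on the diffuse haplotype in spleen (fold interval 1.09 to 1.31). In both tissues all 5 diffuse libraries lay above all 5 single libraries (exact permutation p = 0.00794, adjusted p = 0.0106). Among WT libraries it was 1.38-fold higher (1.19 to 1.64) in spleen, again with all 5 above (exact permutation p = 0.00794, adjusted p = 0.0106). In WT bone marrow it was 1.23-fold higher (1.00 to 1.57), with 3 of 5 diffuse libraries above all single libraries (exact permutation p = 0.0476, adjusted p = 0.0476). The th3/+ ratio on the diffuse haplotype stayed below the WT ratio on either haplotype in both tissues, with a highest library of 1.49 in bone marrow and 1.56 in spleen. The call in WT bone marrow was lost with Hba-a1 alone as the denominator (log2 difference 0.25, exact permutation adjusted p = 0.159) or with Hba-a2 alone (0.27, exact permutation adjusted p = 0.103). It was also lost on leaving out any of 6 of the 10 libraries, which were WT diffuse 1, 2 and 3 and WT single 1, 3 and 4 (log2 differences 0.20 to 0.31). WT haplotypes were also confounded with the series of mouse codes. The 1 WT single mouse coded like the diffuse mice had ratios of 2.66 in bone marrow and 2.14 in spleen, below the lowest WT diffuse libraries of 2.77 and 2.67. The Hbb-single column held 0 exon counts in all 20 diffuse libraries, although these had 363 to 9253 Hbb-bs and 787 to 7217 Hbb-bt counts. The Hbb-diffuse column held 0 in all 20 single libraries. Shared reads may thus have been counted by haplotype label. A difference in read counting cannot be told apart from a haplotype effect here.

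Whether the haplotype changed the size of the th3/+ effect was tested as a difference of log2 differences. In bone marrow the effect differed by -0.01 between the diffuse and the single haplotype (permutation p = 0.959, adjusted p = 0.959). In spleen it differed by -0.20, a larger decrease on the diffuse haplotype (permutation p = 0.0959, adjusted p = 0.192), which did not pass the threshold. With 1 library left out the value ranged from -0.063 to 0.091 in bone marrow and from -0.240 to -0.108 in spleen, and none passed. The spleen value nearest 0 was that without WT diffuse library 5 (permutation adjusted p = 0.400). On the linear scale of the ratio the difference in spleen was -0.57 and passed it (permutation adjusted p = 0.00376), a call that was not tested with libraries left out. Because the WT spleen ratio was higher on the diffuse haplotype (2.94 against 2.12), an equal fold gives a larger linear decrease there.

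The second beta gene took the smaller part of the uniquely assigned exon counts of its pair everywhere, and a larger share in th3/+ than in WT bone marrow. This share of counts is not a share of molecules. Hbb-b2 made up 15.5% ± 0.425 of the diffuse pair in WT and 17.9% ± 0.893 in th3/+ bone marrow (SD, n = 5 each). The log2 odds difference was 0.25 (95% interval 0.15 to 0.36), with all 5 th3/+ libraries above all WT libraries (exact permutation p = 0.00794, adjusted p = 0.0317). Hbb-bt made up 18.9% ± 1.34 of the single pair in WT and 21.3% ± 0.944 in th3/+ bone marrow (SD, n = 5 each). The difference was 0.21 (0.05 to 0.40) with 4 of 5 above (exact permutation p = 0.0238, adjusted p = 0.0317). In spleen Hbb-b2 rose from 16.1% to 17.8% (n = 5 each; log2 odds difference 0.17, exact permutation p = 0.0238, adjusted p = 0.0317), with SDs of 1.2 and 0.470. Hbb-bt in spleen, at 20.2% in WT and 21.04% in th3/+ with SDs of 0.608 and 0.552, did not pass the threshold (log2 odds difference 0.07, n = 5 each, exact permutation p = 0.0635, adjusted p = 0.0635). The effect was not shown to differ between haplotypes (permutation adjusted p = 0.608 in bone marrow and 0.297 in spleen). The Hbb-bt call in bone marrow was lost on leaving out th3/+ single library 1, 3, 4 or 5 (log2 odds differences 0.19 to 0.22, exact permutation adjusted p up to 0.0635). That of Hbb-b2 in spleen was lost without th3/+ diffuse library 3 (0.15, adjusted p = 0.0529). Hbb-bt in spleen passed without th3/+ single library 5 (0.09, adjusted p = 0.0476). In bone marrow the only WT single mouse of the code series of the th3/+ mice had an Hbb-bt share of 19.9%, within the range of 17.2% to 20.2% of the other 4 and above the lowest th3/+ single library at 19.8%. On the single haplotype, genotype and code series were thus confounded for all WT mice but this 1.

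**Figure D2:**
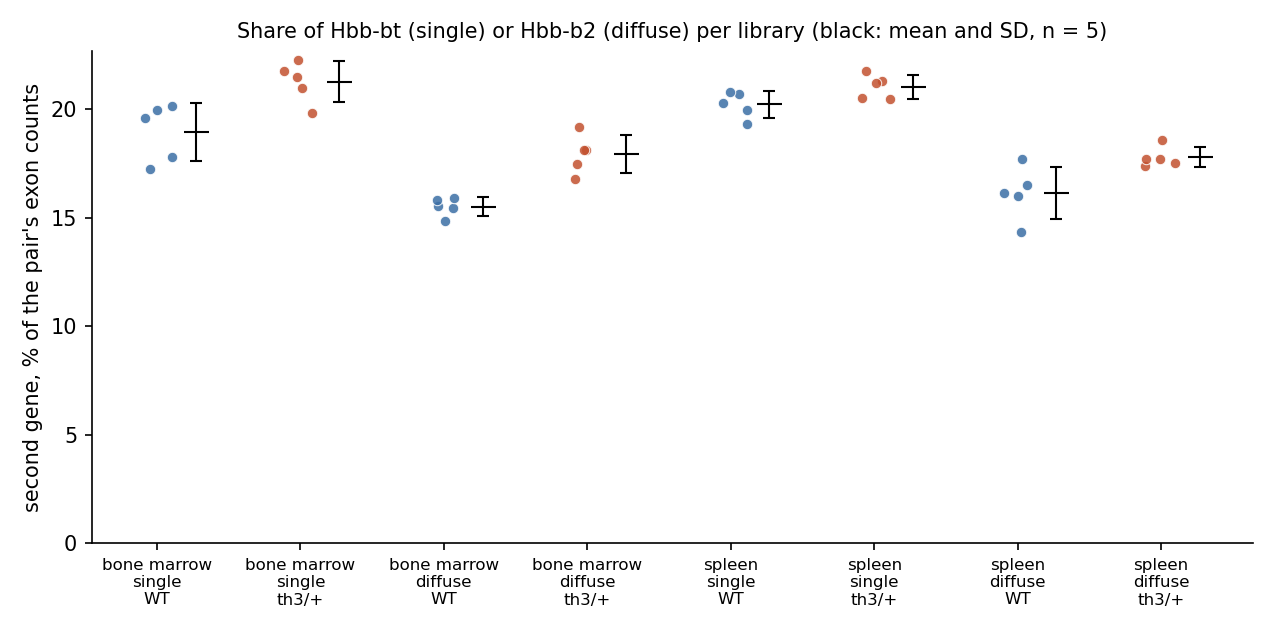
Share of the second gene among uniquely assigned exon counts of the pair (vertical axis, percent), Hbb-bt in single and Hbb-b2 in diffuse libraries, by tissue, haplotype and genotype, with WT in blue, th3/+ in red and group mean and SD in black (n = 5). Diffuse libraries lie between 14.4% and 19.2% and single libraries between 17.2% and 22.3%.

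Between haplotypes, Hbb-b2 took a smaller share of its pair than Hbb-bt did of its own. The log2 odds differences, diffuse against single, were -0.35 (95% interval -0.48 to -0.19) in WT and -0.31 (-0.44 to -0.16) in th3/+ bone marrow. In spleen they were -0.40 (-0.54 to -0.26) in WT and -0.30 (-0.37 to -0.23) in th3/+. In each comparison all 5 diffuse libraries lay below all 5 single libraries (exact permutation p = 0.00794, adjusted p = 0.00794). Between 14.1% and 18.6% of beta counts in single libraries were shared by Hbb-bs and Hbb-bt and entered neither side of this share. A difference between the pairs in length or mappability can thus not be told apart from a haplotype effect on the share.

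Taken gene by gene and relative to alpha counts, the genes of the haplotype carried had fewer counts in th3/+ libraries, past the threshold in 7 of 8 tests. In bone marrow the edgeR log2 fold changes were -1.22 (SE 0.44, adjusted p = 0.0141) for Hbb-bs, -1.22 (SE 0.20, adjusted p = 1.19e-06) for Hbb-b1 and -0.97 (SE 0.23, adjusted p = 0.000252) for Hbb-b2. Hbb-bt in bone marrow fell by 50.1% (SE 0.19 on the log2 scale, edgeR adjusted p = 1.51e-05). In spleen the log2 fold changes were -0.69 for Hbb-bt (SE 0.19, edgeR adjusted p = 0.00145), -1.01 for Hbb-b1 (SE 0.20, adjusted p = 2.28e-05) and -0.83 for Hbb-b2 (SE 0.22, adjusted p = 0.00136). Hbb-bs in spleen at -0.76 did not pass (SE 0.44, edgeR adjusted p = 0.116). All 8 passed when only the groups compared were fitted (Hbb-bs in spleen, edgeR adjusted p = 1.92e-05), a choice made after the data were seen that keeps libraries of the other haplotype out of the spread of each gene. They did so too without th3/+ diffuse bone marrow library 1 (Hbb-bs in spleen, edgeR adjusted p = 0.0408). With the sum of all globin counts as the offset in place of alpha counts, 1 of the 8 passed, and with TMM factors 5 did.

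The alpha genes changed little against each other. Relative to the alpha sum, Hba-a1 was higher in th3/+ than in WT in all 4 comparisons. The log2 differences were 0.10 (SE 0.02, edgeR adjusted p = 0.000451) and 0.06 (SE 0.02, adjusted p = 0.0154) in bone marrow of the single and diffuse haplotypes, and 0.11 (adjusted p = 0.000155) and 0.06 (adjusted p = 0.0216) in spleen. Reads shared by Hba-a1 and Hba-a2, the remaining part of that sum, were lower in th3/+ on the single haplotype, by 0.11 in bone marrow and in spleen (SE 0.04, edgeR adjusted p = 0.0103 and 0.0151). The rise of Hba-a1 there thus went with fewer shared reads. On the diffuse haplotype the shared reads did not pass (-0.08 and -0.02, edgeR adjusted p = 0.0710 and 0.585). The call of the shared reads was lost without WT single bone marrow library 1 (-0.08, edgeR adjusted p = 0.0536), without th3/+ single spleen library 1 (-0.09, adjusted p = 0.0537) and in spleen with DESeq2 (adjusted p = 0.0644). In diffuse bone marrow they passed with DESeq2 (adjusted p = 0.0401) and on leaving out WT library 4 or th3/+ library 2 (edgeR adjusted p = 0.0349 and 0.0196). Hba-a2 passed only in spleen of the diffuse haplotype, where it fell by 0.07 (SE 0.02, edgeR adjusted p = 0.0154), and the other 3 values lay between -0.03 and -0.01. On the diffuse haplotype the Hba-a1 calls were lost without WT bone marrow library 3 (0.05, edgeR adjusted p = 0.0672) and without WT spleen library 5 (0.05, adjusted p = 0.0729). The Hba-a2 call was lost without WT spleen library 4 (-0.04, edgeR adjusted p = 0.0863) or th3/+ spleen library 2 (-0.05, adjusted p = 0.0571). The Hba-a1 call in diffuse bone marrow also ended with DESeq2 (adjusted p = 0.102), and both Hba-a1 calls and the Hba-a2 call of the diffuse haplotype ended with TMM factors (edgeR adjusted p = 0.373, 0.399 and 0.369). With only the groups compared in the fit, edgeR gave an adjusted p of 0.0742 for Hba-a1 in diffuse bone marrow and for Hba-a2 in diffuse spleen. Relative to all globin counts Hba-a2 was higher in th3/+ in all 4 comparisons, by 0.44 to 0.77. Between haplotypes, Hba-a1 was 0.06 higher in diffuse than in single WT spleen (SE 0.02, edgeR adjusted p = 0.0304), with the shared reads 0.10 lower (SE 0.04, adjusted p = 0.0199), and the other 7 tests of the alpha genes did not pass. The unadjusted edgeR p of Hba-a1 there was 0.0224, and an adjustment over the alpha tests alone was not made.

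The comparison of the tissues showed no difference in the beta/alpha ratio that passed the threshold in the unpaired exact test. In WT single mice the ratio was 2.60 ± 0.357 in bone marrow and 2.12 ± 0.178 in spleen (SD, n = 5 each). The log2 difference was -0.29 (95% interval -0.51 to -0.01, exact permutation p = 0.0397, adjusted p = 0.159). The differences were -0.12 (-0.44 to 0.20) in WT diffuse, 0.10 (-0.10 to 0.32) in th3/+ single and 0.07 (-0.04 to 0.18) in th3/+ diffuse mice. Their exact permutation adjusted p lay between 0.254 and 0.437. With 1 library left out these 3 differences ranged from -0.214 to -0.022 in WT diffuse, from 0.045 to 0.146 in th3/+ single and from 0.054 to 0.091 in th3/+ diffuse mice, and none passed. With the mouse code as a block, limma gave the same -0.29 in WT single mice with an adjusted p of 0.0285. Without the block limma gave an adjusted p of 0.0263, so the pairing itself did not change the call in limma. Within mice, 0 of 5 WT single mice had the higher ratio in spleen (exact sign-flip p = 0.0625). That is the smallest p that 5 pairs allow, so the paired exact test could not pass. The WT single difference also passed in the unpaired exact permutation test on leaving out WT single bone marrow library 4 (-0.37, adjusted p = 0.0317).

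Libraries also held small counts assigned to the genes of the haplotype with which the mice were not labelled. In single libraries Hbb-b1 took 143 ± 19.8 counts per 1000000 beta counts in WT and 124 ± 19.8 in th3/+ bone marrow, and Hbb-b2 took 20.98 ± 6.02 and 256 ± 30.1 (SD, n = 5 each). In spleen Hbb-b1 took 463 ± 277 in WT and 157 ± 17.6 in th3/+, and Hbb-b2 took 94.0 ± 64.1 and 202 ± 22.6 (SD, n = 5 each). In diffuse bone marrow Hbb-bs took 52.5 ± 16.1 in WT and 106 ± 117 in th3/+, and Hbb-bt took 257 ± 26.9 and 214 ± 71.2 (SD, n = 5 each). In diffuse spleen Hbb-bs took 263 ± 240 in WT and 63.0 ± 18.9 in th3/+, and Hbb-bt took 254 ± 81.0 and 210 ± 46.3 (SD, n = 5 each). In spleen Hbb-b1 in single and Hbb-bs in diffuse libraries were thus lower in th3/+, with folds of 0.378 (95% interval 0.224 to 0.585, exact permutation adjusted p = 0.0159) and 0.316 (0.116 to 0.765, adjusted p = 0.0476). WT diffuse spleen library 2 had 666 Hbb-bs counts per 1000000 beta counts, against 68.0 to 295 in the other libraries of its group. These calls were not tested with libraries left out. Together, both genes of the haplotype not labelled took at most 1146 of 1000000 beta counts in any library.

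**Figure D3:**
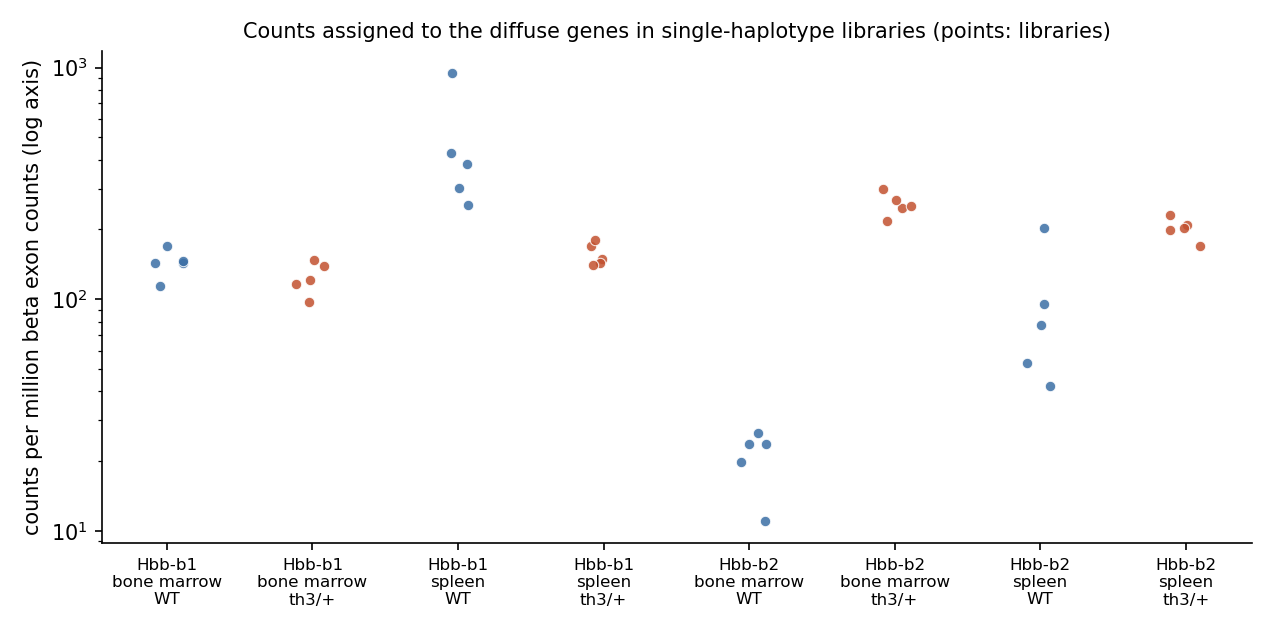
Exon counts assigned to the diffuse-haplotype genes Hbb-b1 and Hbb-b2 in libraries of single-haplotype mice, per 1000000 beta exon counts (log axis), by tissue and genotype, with WT in blue and th3/+ in red and 1 point per library. In bone marrow Hbb-b2 lies between 11.1 and 26.4 in WT and between 217 and 299 in th3/+.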

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

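The tests of the counts assigned to the haplotype not carried, of the tissue difference and of the explanations below were chosen after the results had been seen, except the count over other splits of the libraries, whose outcome was predicted before it was run.

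Hbb-b2 counts in single-haplotype mice stood out because a gene outside the labelled haplotype had higher counts in th3/+ than in the WT libraries. These counts enter the beta sum of the report only as a trace. Per 1000000 beta counts they were 12.7-fold higher in th3/+ than in WT bone marrow (95% interval 9.32 to 19.1) and 2.51-fold higher in spleen (1.32 to 4.58), with exact permutation adjusted p of 0.0159 and 0.0317 (n = 5 each). Beta counts themselves fell in th3/+, which raises these folds. Per alpha count the folds were 5.70 (95% interval 4.10 to 8.07, exact permutation adjusted p = 0.0159) in bone marrow and 1.47 (0.776 to 2.78, adjusted p = 0.198) in spleen, so the call in spleen ended with that denominator. Carry-over from diffuse libraries would bring Hbb-b1 and Hbb-b2 in the proportion of those libraries, where Hbb-b2 was at most 19.2% of the pair, but the lowest Hbb-b2 share in single th3/+ libraries was 53.1%. In WT single spleen the Hbb-b2 share was 16.3% ± 1.72 (SD, n = 5), near the 16.1% of WT diffuse spleen. Carry-over thus stays open for these WT traces. Trace counts need not arise at 1 rate in both genotypes. Hbb-b1 in the same spleen groups was lower in th3/+, at 157 against 463 per 1000000 beta counts. A rate of misassigned reads that differs between libraries would move Hbb-b1 and Hbb-b2 together. The ratio of Hbb-b2 to Hbb-b1 was instead 14.7-fold higher in th3/+ bone marrow (95% interval 12.2 to 19.0) and 6.63-fold higher in spleen (5.46 to 7.997). The ratio of Hbb-bt to Hbb-bs rose by at most 1.32-fold at the upper end of its intervals. An Hbb-bs or Hbb-bt sequence variant of one code series, read as Hbb-b2 alone, cannot be told apart from a genotype effect, because only 1 WT single mouse shared the code series of the th3/+ mice. That mouse speaks against a variant common to the series: its bone marrow library had 26.4 Hbb-b2 counts per 1000000 beta counts against 217 to 299 in th3/+, and an Hbb-b2 share of 13.5% against 65.8% to 69.0%. A variant that not all mice of the series carry stays open. A candidate explanation that also stays open is that some Hbb-b2 sequence remains on the th3 chromosome and is transcribed: Hbb-b2 intron counts were at least 18 in each of the 10 single th3/+ libraries and at most 7 in the 10 single WT libraries. This is a hypothesis found and tested on the same data, and which part of Hbb-b2 the reads covered was not analysed here.

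The higher beta/alpha ratio of the diffuse haplotype depends on how completely reads of near-identical genes were counted. With uniquely assigned counts only, the log2 difference went from 0.30 to 0.52 in WT and from 0.29 to 0.55 in th3/+ bone marrow. In spleen it went from 0.46 to 0.68 in WT and from 0.26 to 0.50 in th3/+ (exact permutation adjusted p = 0.00794 in all 4). Leaving out shared reads takes more beta counts from single than from diffuse libraries. A loss of 16.5% to 27.3% of single-haplotype reads would by itself give the folds seen, and it would act alike on WT and th3/+. The difference between genotypes in the haplotype effect did not pass the threshold (lowest permutation adjusted p of the 2 tissues 0.192), so such a loss and a biological difference between the haplotypes cannot be told apart here. The series of mouse codes does not account for the difference among th3/+ mice, which were all of 1 series and differed with an exact permutation adjusted p of at most 0.0106. Among WT mice it stays open, since 1 WT single mouse shared the series of the WT diffuse mice.

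Of 100 splits by genotype within tissue and haplotype, 1 gave as many beta genes lower in edgeR as the real 7 of 8. It was the real split, and the highest of the others was 2. A chance division of the libraries is thus unlikely for that count but not excluded, since 1 in 100 is the smallest share possible. Labels were shuffled in each tissue apart, although both tissues came from the same mice. A shuffle also adds the genotype effect to the spread, which lowers the counts of the other splits.

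The change from bone marrow to spleen in the log2 beta/alpha ratio differed between genotypes in single-haplotype mice. Within mice it was -0.29 in WT and 0.10 in th3/+, a difference of 0.39 (95% interval 0.13 to 0.64, exact permutation p = 0.0238, adjusted p = 0.0476, n = 5 each). In diffuse mice the difference was 0.19 (-0.17 to 0.55, exact permutation adjusted p = 0.341). Whether 0.39 differs from 0.19 was not tested. In single mice the values ranged from -0.41 to -0.01 in WT and from -0.10 to 0.34 in th3/+, so the ranges overlapped. The call in single mice, near the threshold, was not tested with mice left out. Genotype was confounded with code series in single mice, as only 1 WT single mouse shared the series of the th3/+ mice. From bone marrow to spleen, alpha intron counts per alpha exon count changed 0.4165-fold in WT single mice (exact permutation adjusted p = 0.0317). In th3/+ single mice they changed 0.915-fold (exact permutation adjusted p = 0.677). In diffuse mice they changed 0.375-fold in WT and 0.968-fold in th3/+ (exact permutation adjusted p = 0.127 and 0.778). The point change was thus not particular to WT single mice. Whether this bears on the ratio was not tested.

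In 7 of 64 sets of 5 libraries, 1 library lay far from the other 4, where chance gives about 1 in 20. WT diffuse spleen library 5 had a beta/alpha ratio of 3.76 against 2.67 to 2.80 in the others. A th3/+ diffuse spleen library had an Hbb-b2 share of 18.6% against 17.4% to 17.7%. A th3/+ single spleen library had an Hba-a2 share of 37.9% of Hba-a1 plus Hba-a2 against 38.8% to 39.1%. Hbb-bs counts per 1000000 beta counts were 81.1 in 1 WT diffuse bone marrow library against 43.2 to 47.9, and 315 in 1 th3/+ diffuse bone marrow library against 45.1 to 59.96. Hbb-b1 counts were 944 in 1 WT single spleen library against 255 to 427, and Hbb-bt counts 303 in 1 WT diffuse bone marrow library against 238 to 255.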

How the results depend on the processing

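The decrease of the beta/alpha ratio in th3/+ kept its direction and its side of the threshold under all alternatives run, as did the higher ratio of the diffuse haplotype except in WT bone marrow. Over the results that answer a comparison, 267 of 280 values with 1 library left out and 100 of 106 values under other settings were scored as unchanged. For single genes and the shared alpha reads the counts were 192 of 200 and 92 of 122. A change of sign where neither value passed was also scored as unchanged. One such result was the difference between haplotypes of the th3/+ effect in bone marrow, -0.063 to 0.091 with 1 library left out. The number of beta genes called had a looser rule, under which 5 with TMM factors counted as unchanged from 7. In WT bone marrow the log2 difference between haplotypes was 0.25 with Hba-a1 alone and 0.27 with Hba-a2 alone, no longer past the threshold, and 0.20 to 0.34 with 1 library left out. With 1 library left out the log2 odds difference of the second gene in th3/+ ranged from 0.17 to 0.24 in single bone marrow, from 0.052 to 0.086 in single spleen and from 0.12 to 0.21 in diffuse spleen, and the WT single tissue difference from -0.37 to -0.24. That tissue difference of -0.29 passed with limma, with and without the replicate block by mouse code, which was added later. On the linear scale the difference between haplotypes of the th3/+ effect in spleen was -0.57 and passed. The WT spleen ratio was 2.94 on the diffuse and 2.12 on the single haplotype, so an equal fold gives a larger linear decrease on the diffuse haplotype. This call by itself is thus no sign that the fold differs. How much of the -0.57 comes from the WT ratios was not tested. With the sum of all globin counts as offset, 1 beta gene of 8 passed against 7, since beta counts make up much of that sum, and Hba-a2 turned to higher in th3/+: 0.71 and 0.77 in single and diffuse bone marrow, 0.44 and 0.58 in spleen. The reads shared by the alpha genes turned likewise, to 0.62 and 0.71 in bone marrow and 0.37 and 0.63 in spleen. With TMM factors 5 of the 8 beta genes passed, and Hba-a2 turned to 0.52 in single bone marrow and 0.57 in single spleen, and the shared alpha reads to 0.42 and 0.49. No paired analysis by replicate number was possible because the rows of the table carry no replicate number, and the embryonic globin alternatives were not run because those genes were not analysed here. Depth did not limit the sums, but Hbb-b2 intron counts in single libraries were few.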

Other observations

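All tests in this part were chosen after the data had been seen.

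Intron counts, which come from unspliced RNA or DNA, showed the same direction as exon counts. The intron beta/alpha ratio was lower in th3/+ than in WT by a fold of 0.514 (95% interval 0.466 to 0.564) and 0.546 (0.466 to 0.645) in bone marrow of the single and diffuse haplotypes. In spleen the folds were 0.452 (0.406 to 0.503) and 0.383 (0.229 to 0.568). Each of the 4 comparisons passed (exact permutation p = 0.00794 and adjusted p = 0.00794, n = 5 against 5). The intron ratio was 2.59-fold and 2.75-fold higher on the diffuse haplotype in WT and th3/+ bone marrow. It was 3.23-fold and 2.74-fold higher in spleen, and all 4 passed (exact permutation adjusted p = 0.00794, n = 5 against 5). These folds compare introns of different genes, and the introns of Hbb-b1 and Hbb-b2 were not in the annotation used. In WT bone marrow beta intron counts were 0.128% of beta exon counts in diffuse and 0.0642% in single libraries. A difference between the genes in intron length or mappability can thus not be told apart from a haplotype effect. In WT diffuse spleen 2 libraries had intron ratios of 4.14 and 4.99 against 2.01 to 2.17 in the other 3, and the same 2 had the lowest alpha intron shares, 0.0242% and 0.0302% of alpha exon counts. They raise the WT diffuse mean behind the folds of 0.383 and 3.23, although all 5 libraries lay above the highest th3/+ diffuse library at 1.26 and the highest WT single library at 0.984. Whether the th3/+ effect differed between exons and introns did not pass the threshold in any of 4 comparisons (exact permutation adjusted p from 0.0952 to 0.246).

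Hba-a2 took a smaller share of uniquely assigned alpha counts in th3/+ than in WT. In bone marrow it was 39.7% ± 0.813 in WT and 37.9% ± 0.350 in th3/+ mice of the single haplotype, and 39.5% ± 0.666 and 38.2% ± 0.856 on the diffuse haplotype (SD, n = 5 each; exact permutation adjusted p = 0.0106 and 0.0317). In spleen it was 41.1% ± 0.716 and 38.7% ± 0.445 on the single, and 40.7% ± 0.886 and 38.6% ± 0.660 on the diffuse haplotype (SD, n = 5 each; exact permutation adjusted p = 0.0106 in both). No difference between haplotypes passed (exact permutation adjusted p = 0.683 in all 4 comparisons).

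The intron share of alpha counts varied most among WT spleen libraries. Alpha intron counts as a percent of alpha exon counts ranged from 0.0242 to 0.208 in the 10 WT spleen libraries, 8.58-fold from lowest to highest, against 1.98-fold in WT bone marrow, 1.70-fold in th3/+ spleen and 2.06-fold in th3/+ bone marrow (n = 10 each). The exact binomial 95% interval of the lowest library was 0.0231% to 0.0253%, which covers counting error only.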
